A study of Drosophila melanogaster with 24 samples.

How the data were processed

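The study measured RNA of whole adult flies of 2 Drosophila melanogaster lines on 2-colour spotted arrays. Each line is heterozygous for a deletion on arm 3L, Df(3L)ED4475 or Df(3L)ED4543, made in the DrosDel collection, in which deletions were built on an isogenic background and are marked by a white gene. Both lines carry the TM6C balancer, a rearranged chromosome that keeps the deletion in the stock. Per the labels, each sample was total RNA of 25 flies aged 2 to 5 days and raised at 26 °C, with 12 samples of each line. Each of the 12 arrays carried a sample of each line under the same label number, with the dyes Cy3 and Cy5 alternated between the lines, so that each line was the control of the other. The sex of the flies is not given in the sources used here.

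The scanner tables deposited by the authors give, for each of 32448 spots, the mean intensity of the spot and of its local background in both channels, per the file headers, with no normalization. They also give the percent of saturated pixels and a quality mark per spot. A flag of that mark fell on between 3107 (array 3) and 13951 (array 6) spots of an array, and these were not left out for it. The value table deposited by the authors holds intensity per probe. Set against the scanner values, each of its 24 columns equalled the spot mean less the local background mean, averaged over the spots of a name, less the mean of the blank spots of that array and channel, within a tolerance of 0.01 for 100.0% of the probes in every column. Its columns were not scaled between arrays, with medians from -21.86 (array 5, line labelled Df(3L)ED4543) to 334.3 (array 8, the same line). That comparison settled scale, centring and direction. A further table deposited by the authors holds a ratio of means, the natural log of the mean intensity and a mark of 0 or 1 whose meaning is not stated. The deposited ratio was found to be the mean of the samples labelled Df(3L)ED4543 over the mean of those labelled Df(3L)ED4475 up to a constant factor of 1.017, which held within 1 percent for 99.2% of the probes. The scanner software version and the genome build are not given in the sources used here.

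From the scanner intensities, background was corrected with normexp and an offset of 50, and log2(Cy5/Cy3) was normalized by loess within each array, with control spots given no weight, in limma 3.58.1 under R 4.3.3. The offset pulls the ratios of dim spots towards 0. Every ratio was then turned to Df(3L)ED4475 over Df(3L)ED4543, so that a positive log2 ratio means more signal from the samples labelled Df(3L)ED4475. Duplicate spots of a probe were averaged. A probe was detected in a channel when its signal lay above the 95th percentile of the 1172 blank spots of that array and channel. Probes detected in either channel on at least 6 of the 12 arrays were kept, which left 6132 probes, and the brightest probe stood for each of 5941 genes. Array 1 had the lowest share of detected probes, 19.5% in Cy5, and array 8 the highest, 62.5% in Cy5. For arrays, the number of arrays limits the precision. Whether the 12 samples of a line came from separate cultures is not given, so the p-values measure only the spread between these samples, which may be technical.

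Gene names came from the CG and CR numbers on the arrays, of which there were 13820. A total of 13200 were matched to the reference gene table of the assembly Release 6 plus ISO1 MT, 12047 by locus tag and 1153 by a synonym. Another 189 matched several genes and kept the name on the array. Because no build is named with the array files, only gene names, arms and the order of neighbouring genes were taken from that table, and no coordinates are given. The deletions were placed by their cytological limits, 68C13 to 69B4 for Df(3L)ED4475 and 70C6 to 70F4 for Df(3L)ED4543, through genes whose symbols or synonyms carry a cytological band. Genes between the last one certainly inside and the first one certainly outside were held apart as margin genes and entered neither set. The arrays held 87 genes of the Df(3L)ED4475 set and 25 of the Df(3L)ED4543 set, of which 33 and 8 passed the detection filter.

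The test between the lines was limma's moderated test with the line coded by its dye and a constant dye term, and Benjamini-Hochberg adjustment over the 5941 genes at an adjusted p of 0.05. For each deletion, the median log2 ratio of its genes on each array, less the median of the genes outside both deletions, was tested over arrays by an exact two-sided sign-flip permutation test. The smallest p this test can give is 0.0625 with 5 arrays and 0.0156 with 7. Set tests were camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Relations across genes or arrays used Spearman's and Pearson's correlation with permutation p-values (100000 permutations, or all orders for small sets). The label numbers 1 to 5 and 6 to 12 were treated as separate array series because the naming of the deposited arrays changes between them, and each comparison was repeated within each series. The same label number was a shared array: the intensities of its pair of samples, as deviations from their line means, correlated between 0.84 and 0.97, and for each of the 12 numbers the own number correlated best.

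Named genes were chosen by a rule fixed before the data were examined. It took the 5 largest and 5 smallest drops with a gene symbol in each deletion, up to 4 members with the smallest p of each gene list, always white (w), and, outside the deletions, the 10 highest and 10 lowest genes past the threshold with the same direction on all arrays, of which there were 0. Genes named outside that rule were chosen after their values were seen. The 22 gene lists, also fixed beforehand, were egg shell and yolk, ovary, accessory gland, testis, X dosage compensation with Pof, Polycomb and Trithorax groups, cytosolic and mitochondrial ribosomal proteins, proteasome, heat shock proteins and chaperones, immune effectors, cytochrome P450, glutathione and UDP transferases, digestive hydrolases, phototransduction, odorant binding and pheromone, muscle contraction, glycolysis, circadian clock, cuticle proteins, larval serum and storage proteins, and histones. Deleted genes were left out of them. In a change from the plan, genes next to the deletions were taken as the 20 nearest tested genes on each side and not by distance, since no coordinates were used. The plan also called for leaving out probes flagged as outliers by the scanner output. Flagged spots were kept, other than those marked as absent from the array.

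The fit was tested on simulated data made from the 12 arrays with 5941 genes. It recovered 95% of 100 genes changed by 0.5 on the log2 scale and 98% of 100 genes changed by 1, with 13 false calls. The simulation drew independent noise for each gene and added the changes to normalized ratios. It thus held no compression by background or offset and no variation shared between genes. These shares are not the power of the real test, in which LManV at 0.58 and CG6277 at 0.55 did not pass. Alternatives covered background correction (none, plain subtraction with spots at or below background left out), normalization (median centring, print-tip loess), the detection filter, the choice of probe, the array series, the deposited value table, the fit without the shared array, and leaving out each array in turn. After the data had been examined, normexp without the offset, plain subtraction joined with the stricter filter (both channels on at least 10 of 12 arrays) and plain subtraction within each array series were added. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.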

Results

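RNA of whole flies heterozygous for Df(3L)ED4475 or Df(3L)ED4543 was compared on 12 two-colour arrays, with 12 samples per line. In each line the genes inside its own deletion are present in 1 copy and the genes inside the other deletion in 2 copies. The series asked whether transcription in such heterozygotes makes up for the missing copy. Signal differed widely between arrays. The share of probes detected was between 19.5% and 27.5% on arrays 1 to 3, between 25.7% and 33.3% on arrays 6 and 7, and reached 62.5% on array 8.

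The genes of each deletion were examined first, because they check the labels. On arrays 1 to 5, the Df(3L)ED4475 genes did not lie lower in the samples labelled Df(3L)ED4475. Their median log2 ratio was between -0.02 and 0.03 on every one of these arrays, with a mean of 0.01 ± 0.02 (SD, n = 5). On arrays 6 to 12 they lay lower in these samples on 6 of 7 arrays, with a mean of -0.10 ± 0.11 (SD, n = 7), array 8 being the exception at 0.05. The mean differed between the array series by 0.11 (exact permutation p = 0.0404 over 792 splits). The Df(3L)ED4543 genes lay lower in the samples labelled Df(3L)ED4543 on 4 of arrays 1 to 5, up to 0.82 on array 5, and on 6 of arrays 6 to 12, up to 0.31 on array 8. Array 1 counts among the 4 at only 0.01, and array 3 had -0.01. With plain subtraction array 1 had -0.25, and 3 of the 5 arrays were lower. On arrays 1 and 3 the genes of neither deletion showed a clear drop. The region check thus does not bear out the Df(3L)ED4475 label on arrays 1 to 5, and bears out neither label on arrays 1 and 3. A missing drop is not by itself evidence against a label, since compensation for the missing copy would also give it. The lines are therefore named below as the samples labelled with them, and every direction rests on those labels.

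**Figure D1:**
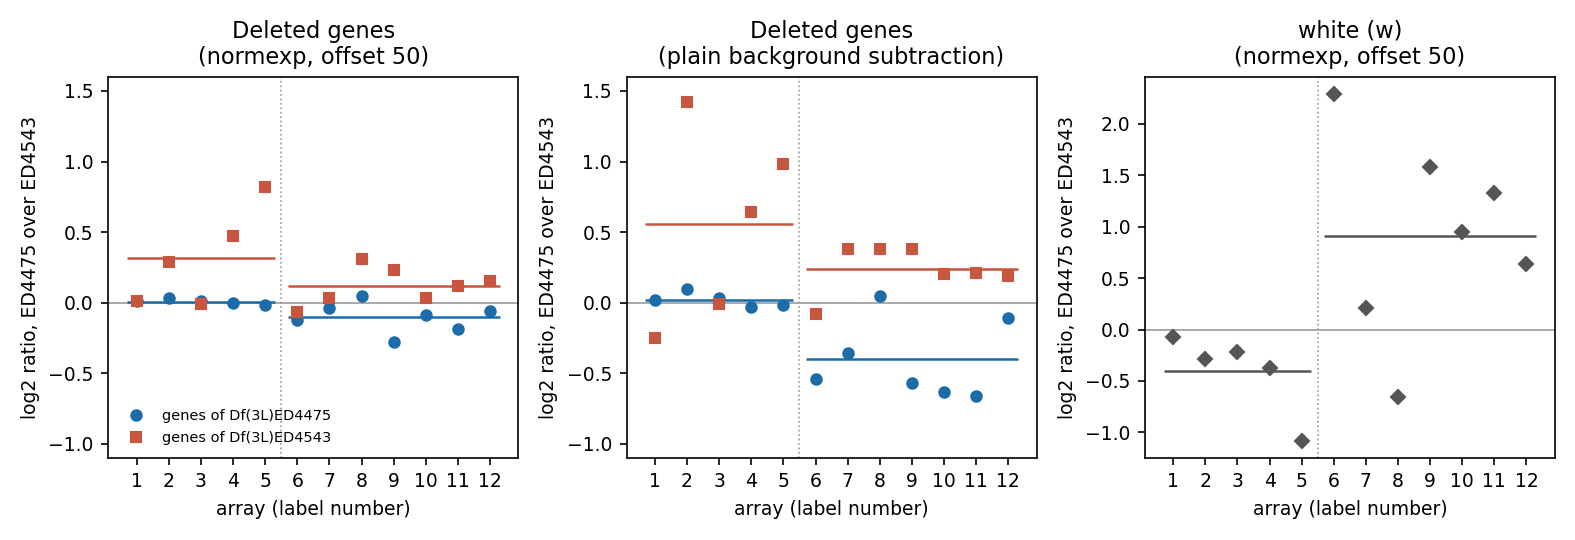
Median log2 ratio (Df(3L)ED4475 over Df(3L)ED4543) of the deleted genes on each of the 12 arrays after normexp with offset 50 (left) and after plain background subtraction (middle), and of white (right). Horizontal lines are means within arrays 1 to 5 and 6 to 12. The Df(3L)ED4475 genes sit at 0.01 on average on arrays 1 to 5 and at -0.10 on arrays 6 to 12 in the left panel, and white goes from a mean of -0.41 to 0.91.

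White (w, CG2759, arm X) encodes an eye pigment transporter and marks the DrosDel deletion chromosomes. Its log2 ratio was negative on 5 of 5 arrays in the first series, with a mean of -0.41 ± 0.39 (SD, n = 5), and positive on 6 of 7 in the second, with a mean of 0.91 ± 0.96 (SD, n = 7). The means differed (exact permutation p = 0.0215). With plain subtraction they were -2.15 and 1.80 (exact permutation p = 0.00379), and the interaction of line and series did not pass limma's test over all genes (adjusted p = 0.437). Array 8 had -0.66 against the other arrays of its series. Over all 12 arrays w had 0.36 ± 0.25 (SE), limma adjusted p = 0.625. On arrays 1, 3, 4 and 5 its signal in the samples labelled Df(3L)ED4475 was below the limit set by the blank spots, and in the samples labelled Df(3L)ED4543 it was below that limit on arrays 1, 4, 6 and 7. Array 6 had the highest ratio, 2.29. On these arrays the ratio does not measure a fold, and with plain subtraction array 1 had 0.15.

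Over all arrays, the genes deleted in Df(3L)ED4475 lay slightly lower in the samples labelled with that deletion, and the difference did not exceed the spread between arrays. The 33 tested genes of 68C13 to 69B4 had a mean over arrays of -0.06 ± 0.10 (SD, n = 12; two-sided sign-flip permutation p = 0.0591), and 24 of the 33 were lower. A loss in proportion to copy number would give a log2 ratio of -1. With the offset, the largest drops were those of CycA, a mitotic cyclin, with 0.46 ± 0.15 (SE), Ak1, an adenylate kinase, with 0.38 ± 0.12, yps, a Y-box RNA-binding protein, with 0.38 ± 0.15, Lsp2, a larval serum protein, with 0.37 ± 0.18, and ND-SGDH, a subunit of mitochondrial complex I, with 0.29 ± 0.15. At the other end, Miox, which encodes an inositol oxygenase, had a drop of -0.49 ± 0.12, and the mucin gene Muc68D -0.08 ± 0.11, vers -0.04 ± 0.06, Cubn2 -0.03 ± 0.04 and Pop2, a deadenylase subunit, -0.03 ± 0.07. The order changed with plain subtraction: thoc6 had the largest drop, 1.08 ± 0.29, then viaf (0.88 ± 0.22) and Ak1 (0.85 ± 0.28). CycA then had 0.49 ± 0.18 and ND-SGDH 0.16 ± 0.31. The set test camera gave p = 0.00016 with the preset correlation, p = 0.0868 with an estimated correlation, and fry gave p = 0.0504. With plain background subtraction, the mean over arrays was -0.23 ± 0.30 (n = 12, permutation p = 0.0376), and within arrays 6 to 12 it was -0.40 ± 0.28 (n = 7, exact permutation p = 0.0312).

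Over all arrays, the genes deleted in Df(3L)ED4543 lay lower in the samples labelled Df(3L)ED4543, by less than the loss of a copy would give in proportion. The 8 tested genes of 70C6 to 70F4 had a mean log2 ratio of 0.20 ± 0.25 (SD, n = 12; two-sided sign-flip permutation p = 0.00879). They lay in that direction on 10 of 12 arrays, array 1 at only 0.01 (9 of 12 with plain subtraction), with 7 of the 8 genes lower. Mpcp2, a mitochondrial phosphate carrier, had a drop of 0.38 ± 0.14 (SE), Gbs-70E, a glycogen-binding subunit of protein phosphatase 1, 0.32 ± 0.08, saturn 0.20 ± 0.08, the fat body gene Fbp1 0.15 ± 0.21, nuf 0.15 ± 0.11, and Sox21a, a transcription factor of intestinal stem cells, -0.06 ± 0.09. The 2 genes without a symbol, CG7768 and CG3868, had 0.34 ± 0.09 and 0.31 ± 0.13. Camera gave p = 7.2e-05 with the preset correlation and p = 0.0336 with an estimated correlation, and fry p = 0.0147. The mean was 0.32 ± 0.35 on arrays 1 to 5 (n = 5, exact permutation p = 0.188) and 0.12 ± 0.13 on arrays 6 to 12 (n = 7, exact permutation p = 0.0781), and these did not differ beyond the spread between arrays (exact permutation p = 0.188). With plain subtraction it was 0.55 ± 0.69 (n = 5, exact permutation p = 0.25) on arrays 1 to 5 and 0.24 ± 0.17 (n = 7, exact permutation p = 0.0312) on arrays 6 to 12. The first of these means covers unlike arrays: arrays 2, 4 and 5 had 1.42, 0.64 and 0.98, and arrays 1 and 3 had -0.25 and -0.01.

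No single deleted gene passed limma's test over all genes, 0 of 33 and 0 of 8 at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 8 (7 lower and 1 higher in the samples labelled Df(3L)ED4475) and 5 (all lower in those labelled Df(3L)ED4543). Adjusted over the list alone, 4 genes of Df(3L)ED4475 were lower: Nrx-IV, a septate junction protein (0.26 ± 0.05 SE, lower on 12 of 12 arrays, adjusted p over the list 0.0037), Ak1, thoc6 and the translation initiation factor subunit eIF3l (each at 0.046). Miox was higher at 0.0201. For Df(3L)ED4543, Gbs-70E (0.00911), CG7768 (0.00951) and Mpcp2 (0.0405) were lower. These names beyond the fixed rule were taken after their values were seen. The 95% intervals of the gene ratios excluded a drop of 1, the loss in proportion to copy number, for all 33 and all 8 genes with the offset. They excluded 1 but not 0 for 25 of the 33 and 3 of the 8, and both for 8 and 5. The 8 include Miox, which was higher in the samples labelled Df(3L)ED4475 (interval of the drop -0.74 to -0.23). Those intervals hold for offset ratios that understate the change of dim genes. With plain subtraction on arrays 6 to 12, 11 of the 33 Df(3L)ED4475 genes excluded 0 but not 1, 15 excluded 1 but not 0, 2 excluded both and 5 neither, and their median drop was 0.49. There thoc6 had a drop of 1.09 ± 0.33 (SE) and the spermine synthase gene Sms 1.14 ± 0.25. With plain subtraction on arrays 1 to 5, the 8 Df(3L)ED4543 genes had a median drop of 0.99, with 3 that excluded 0 only, 2 that excluded 1 only and 3 neither, and Gbs-70E had 1.32 ± 0.27. In the other series the same setting gave lower values: a median drop of 0.20 for the Df(3L)ED4543 genes on arrays 6 to 12, where 5 of 8 excluded 1 only, and of -0.08 for the Df(3L)ED4475 genes on arrays 1 to 5, where 24 of 33 did. Over all 12 arrays the median drop with plain subtraction was 0.41 for Df(3L)ED4543 and 0.18 for Df(3L)ED4475.

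**Figure D2:**
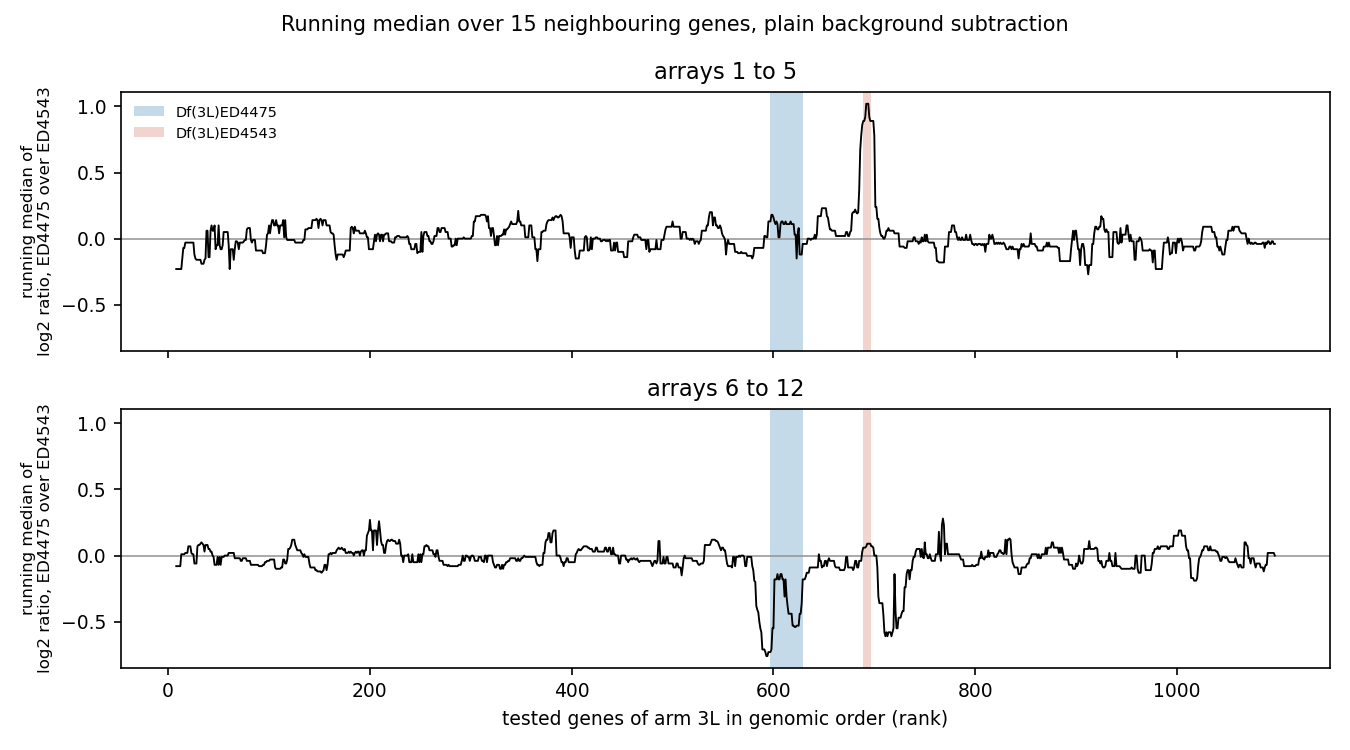
Running median over 15 neighbouring tested genes of the log2 ratio (Df(3L)ED4475 over Df(3L)ED4543, plain background subtraction) along arm 3L in gene order, for the mean of arrays 1 to 5 (top) and 6 to 12 (bottom). Shaded bands span the genes certainly inside each deletion. The highest value is 1.02 at saturn on arrays 1 to 5, and the lowest is -0.76 at Pldn, a margin gene of Df(3L)ED4475, on arrays 6 to 12.

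The ratio of means in the authors' deposited table, which is turned the other way (Df(3L)ED4543 over Df(3L)ED4475), had a median of 0.905 over the 87 Df(3L)ED4475 probes, 0.94 over the 25 Df(3L)ED4543 probes and 1.041 over the 12968 probes outside. The value of the Df(3L)ED4543 probes rests on the 7 with a censor mark of 1, whose meaning is not stated, at 0.764, while the 18 with mark 0 had 1.043, against 1.046 outside. For the Df(3L)ED4475 probes this direction is opposite to that of the within-array log2 ratios above, which cover the 33 genes that passed the filter and not all 87 probes. Taken within arrays, the deposited values gave -0.16 for these genes, in the direction of the log2 ratios above (permutation p = 0.131). The deposited ratio averages linear intensities over arrays that were not scaled to each other, so bright arrays weigh most in it, and array 8 was the brightest.

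The drops of the 2 deletions were compared on each array. That of the Df(3L)ED4475 genes was smaller by 0.14 on average, -0.14 ± 0.29 (SD, n = 12), a difference within the spread between arrays (sign-flip permutation p = 0.112). A permutation of the deletion labels over the 41 genes gave p = 0.0319, but genes are not independent replicates. On arrays 1 to 5 the difference was -0.32 ± 0.33 (n = 5, exact permutation p = 0.0625, the smallest that 5 arrays allow) and on arrays 6 to 12 it was -0.01 ± 0.17 (n = 7, exact permutation p = 0.906). The series differed by -0.31 (exact permutation p = 0.0556), and by -0.74 with plain subtraction (exact permutation p = 0.0391).

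Over all arrays, the drop of a deleted gene had no detected relation to its expression level. Across the 33 Df(3L)ED4475 genes, Spearman's rho between the drop and the intensity in the line with 2 copies was 0.09 (permutation p = 0.604) and Pearson's r 0.07 (p = 0.676), and without the 2 genes farthest from the median intensity they were 0.25 and 0.27. Across the 8 Df(3L)ED4543 genes rho was 0.62 (exact permutation p = 0.115) and r 0.50 (exact permutation p = 0.168), and 0.54 and 0.47 without the 2 farthest genes. Over all 41 genes rho was 0.19 (permutation p = 0.228) and r 0.13 (p = 0.419), and 0.22 and 0.16 without 2 genes. The adjusted p of the 3 Spearman tests were 0.604, 0.342 and 0.342. These relations are across genes, which are not independent replicates. With plain subtraction the sign of rho turned, to -0.15, -0.14 and -0.13. Other settings passed the threshold: rho was 0.37 (permutation p = 0.0354) for Df(3L)ED4475 on arrays 6 to 12, and without a filter 0.39 for Df(3L)ED4475 and 0.55 for Df(3L)ED4543. Without array 5 it was 0.81 for Df(3L)ED4543 (n = 8, exact permutation p = 0.0218). All these values use the intensity of the line with 2 copies, which shares error with the drop and so can raise rho. With the mean intensity of both lines and all arrays, rho was 0.05 for Df(3L)ED4475 (permutation p = 0.794). For Df(3L)ED4543 it was 0.36 (exact permutation p = 0.389), and over all 41 genes 0.13 (permutation p = 0.425). Without the 2 farthest genes it was 0.19 for Df(3L)ED4475 and 0.03 for Df(3L)ED4543.

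Outside both deletions, 0 of 5719 genes differed between the lines by limma's test, and 653 had an unadjusted p under 0.05. Over all 5941 genes 0 passed, the lowest adjusted p was 0.155, and 689 (11.6%) had an unadjusted p under 0.05, 432 of them higher in the samples labelled Df(3L)ED4475 and 257 lower. The lowest p belonged to LManV (CG9466, arm 2L), an alpha-mannosidase, with 0.58 ± 0.09 (SE), adjusted p = 0.155, positive on 12 of 12 arrays. This gene was named after its values were seen. Within arrays 1 to 5, 0 genes passed and 307 had an unadjusted p under 0.05, and within arrays 6 to 12 these were 0 and 672. Arm medians lay between -0.01 on X and on 4 and 0.02 on Y, with 0 genes called on any arm. The value of Y rests on 2 genes. The 20 tested genes on each side of the deletions had medians between -0.08 and 0.01 over all arrays, with 0 called. On arrays 6 to 12 the 20 genes to the right of Df(3L)ED4543, from CG13465 to AGO2, had -0.14, and -0.51 with plain subtraction.

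Genes limited to the male germline lay higher in the samples labelled Df(3L)ED4475 by the test over arrays, but not by camera with an estimated correlation (adjusted p = 0.214). Egg shell and ovary genes had negative medians that did not exceed the spread between arrays. The testis list had a median log2 ratio of 0.34 over 20 genes, 19 of them higher, among them the sperm protein genes Mst84Db (0.53 ± 0.12 SE), Mst84Dc (0.52 ± 0.12) and Mst77F (0.39 ± 0.09) and the leucyl aminopeptidase S-Lap7 (0.43 ± 0.10). The list was positive on 12 of 12 arrays, with a mean of 0.32 ± 0.32 (SD, n = 12; sign-flip permutation p = 0.000488, the smallest that 12 arrays allow, adjusted over the lists 0.0107), 0.41 on arrays 1 to 5 and 0.26 on arrays 6 to 12. Its size was uneven, between 0.02 and 0.10 on arrays 1, 3, 4, 6, 10 and 11 and highest on arrays 2 (0.89) and 5 (0.91). The accessory gland list, seminal fluid genes of the male, had 0.34 over 19 genes, with Acp36DE at 0.36 ± 0.10, Acp53Ea at 0.40 ± 0.12, Mst57Da at 0.39 ± 0.12 and Acp26Aa at 0.37 ± 0.11, and was positive on 9 of 12 arrays (permutation p = 0.0347, adjusted 0.308). The egg shell and yolk list had -0.24 over 18 genes, 17 of them lower, with the chorion genes Cp7Fb at -0.39 ± 0.15, Cp7Fa at -0.30 ± 0.13, Cp7Fc at -0.35 ± 0.16 and Fcp3C at -0.27 ± 0.12, and the ovary list -0.06 over 21 genes, with osk at -0.19 ± 0.06, otu at -0.24 ± 0.09, swa at -0.20 ± 0.10 and pum at -0.09 ± 0.05. Over arrays, no difference from 0 was detected for either female list: egg shell was positive on 5 of 12 arrays (permutation p = 0.279, adjusted 0.472) and ovary on 3 of 12 (p = 0.246, adjusted 0.472). On arrays 1 to 5 the median over genes was 0.0039 for egg shell and -0.00359 for ovary, and on arrays 6 to 12 it was -0.33 and -0.10. Adjusted over the list alone, 18 testis and 13 accessory gland genes were higher and 0 egg shell or ovary genes were lower, against 0 of each over all genes tested.

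**Figure D3:**
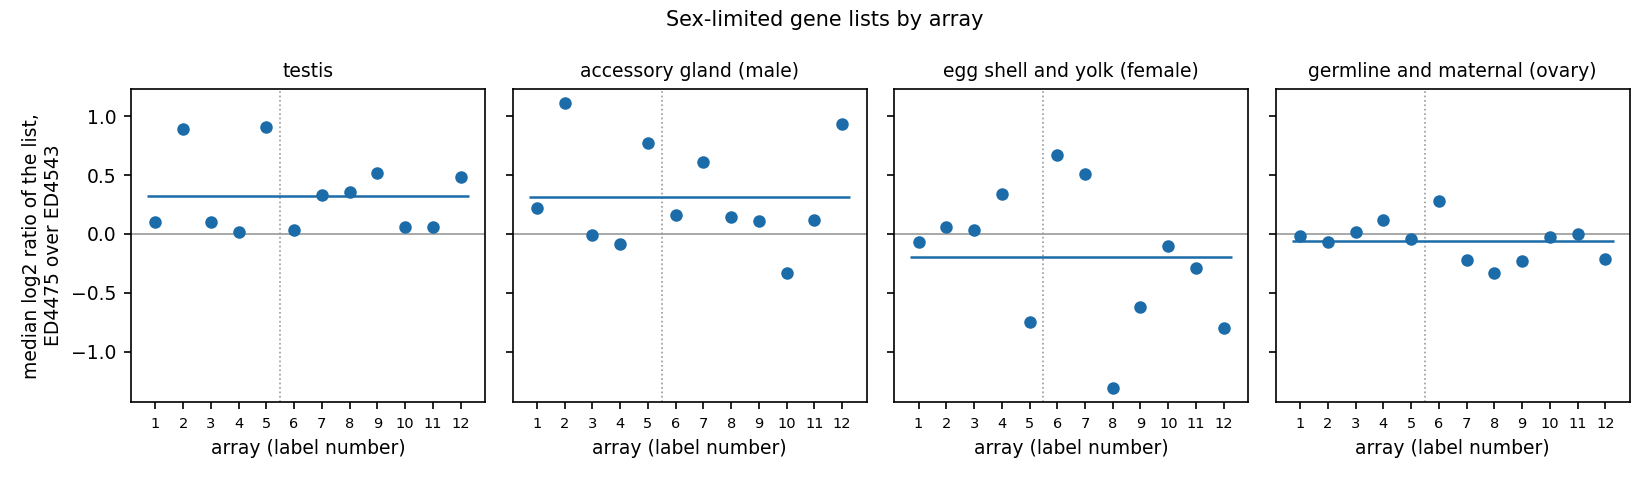
Median log2 ratio (Df(3L)ED4475 over Df(3L)ED4543) of 4 sex-limited gene lists on each of the 12 arrays, with the mean over arrays as a horizontal line and a dotted line between the array series. The testis list is above 0 on 12 of 12 arrays with a mean of 0.32.

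By camera with the preset correlation, 9 of the 22 lists passed an adjusted p of 0.05, 5 higher and 4 lower in the samples labelled Df(3L)ED4475. These were testis (adjusted p = 1.16e-16), accessory gland (4.26e-11), egg shell and yolk (0.00428), ovary (0.0224), proteasome (median -0.05, 0.00202), heat shock proteins and chaperones (-0.08, 0.00824), glutathione and UDP transferases (0.07, 0.00824), digestive hydrolases (0.03, 0.00824) and cytochrome P450 (0.03, 0.0353). With an estimated correlation 0 of the 22 passed: adjusted p = 0.214 for testis, 0.422 for accessory gland and for the transferases, and 0.625 or 0.632 for the other 6. Fry called testis alone (adjusted p = 0.0376). Medians depended on single arrays: on leaving out 1 array that of egg shell ranged from -0.28 to -0.12 (adjusted p up to 0.111), that of P450 from 0.02 to 0.09 (adjusted p up to 0.172), that of digestive hydrolases from 0.02 to 0.07 (up to 0.0729) and that of ovary from -0.09 to -0.03 (up to 0.108). Transferases ranged from 0.04 to 0.07, heat shock from -0.10 to -0.05 and proteasome from -0.08 to -0.04, and these kept their calls. Of 30 alternatives, P450 lost its call in 10 and turned sign in 2. In the digestive list, which holds gut enzymes, 8 of 35 genes were higher adjusted over the list alone, among them the maltases Mal-A3 (0.39 ± 0.09 SE), Mal-A1 (0.35 ± 0.09) and Mal-A6 (0.38 ± 0.11) and the protease Jon99Ci (0.25 ± 0.06). In the P450 list Cyp9f2 (0.29 ± 0.07) passed in that way, and Cyp6a13 (0.14 ± 0.05), Cyp12a4 (0.21 ± 0.08) and Cyp6g1 (0.23 ± 0.10) did not. Of the transferases, Ugt35B1 had 0.27 ± 0.07, GstD1 0.23 ± 0.07, GstE9 0.18 ± 0.07 and Ugt50B3 0.23 ± 0.08, and 0 passed over the list alone. The heat shock genes Hsp27 (-0.26 ± 0.12), Hsp23 (-0.31 ± 0.15), Hsp26 (-0.26 ± 0.16) and Hsc70-4 (-0.09 ± 0.06) did not pass either. Of the proteasome list 31 of 35 genes had negative ratios, with Rpn3 at -0.15 ± 0.05, Rpn10 at -0.13 ± 0.05 and Prosalpha7 at -0.12 ± 0.05, while the testis form Prosalpha3T had 0.20 ± 0.07.

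The other 13 lists did not pass over all arrays. Their medians were -0.03 for X dosage compensation with Pof, a protein of chromosome 4, (adjusted p = 0.452, with a mean of 0.09, opposite in sign), -0.04 for the Polycomb and Trithorax groups (0.318), 0.02 for cytosolic ribosomal proteins (0.0952), -0.02 for mitochondrial ribosomal proteins (0.0813), 0.03 for immune effectors (0.318), 0.05 for phototransduction (0.228), 0.05 for odorant binding and pheromone (0.0616), and -0.05 for muscle contraction (0.0952). They were 0.04 for glycolysis (0.318), 0.02 for the circadian clock (0.318), 0.00089 for cuticle proteins (0.616), 0.04 for larval serum and storage proteins (0.917, with a mean of -0.00489) and -0.02 for histones (0.571). Within the X dosage list, roX1, a male-specific RNA of the X dosage compensation complex, had 0.43 ± 0.12 (SE), positive on 10 of 12 arrays, and passed over the list alone (adjusted p = 0.0209, limma). In the clock list the cryptochrome cry had 0.17 ± 0.04 and passed in the same way (0.0127).

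Within the array series some of these lists passed camera with the preset correlation, 7 of 22 lists on arrays 1 to 5 and 16 on arrays 6 to 12. Muscle contraction genes had a median of -0.27 on arrays 1 to 5 (adjusted p = 3.43e-19, 28 of 29 negative) and 0.04 on arrays 6 to 12 (0.246). Cytosolic ribosomal proteins had 0.10 (9.82e-11) and -0.02 (0.038), immune effectors -0.23 (0.0112) and 0.20 (0.000704), and phototransduction genes -0.08 (0.00651) and 0.12 (0.0108), so that the medians of these 3 lists had opposite signs in the series. Larval serum and storage proteins had -0.19 on arrays 1 to 5 (0.0077). On arrays 6 to 12 the Polycomb and Trithorax groups had -0.06 (0.038), mitochondrial ribosomal proteins -0.03, odorant binding and pheromone genes 0.07 and glycolysis 0.09 (each 0.0207). With an estimated correlation 0 of these passed: the adjusted p of these lists lay between 0.430 and 0.742 in the series where they were called. Tested over arrays, the difference between the series did not pass for muscle (exact permutation p = 0.331), ribosomal proteins (0.271), immune effectors (0.133) or phototransduction (0.141). The lowest p was that of cytochrome P450, with means of -0.03 and 0.10 (exact permutation p = 0.0189), which did not pass after adjustment over the lists (0.417).

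The effect of the array series on single genes was tested as the interaction of line and series. By limma 0 of 5941 genes passed, with 356 at an unadjusted p under 0.05. With plain subtraction 1 of 5903 passed, Npc2g, a lipid-recognition protein family gene, with a mean of -1.91 on arrays 1 to 5 and 0.17 on arrays 6 to 12 (adjusted p = 0.00919), and 418 had an unadjusted p under 0.05.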

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

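The tests of the array series, of the missing drop on arrays 1 to 5, of chance over arrays for the testis list, of the correlation of sex-limited lists and of the splits for lists and within series were chosen after the results were seen, as were the rules that the female lists must also differ from 0 over arrays and that a real count of 0 decides nothing. The tests of compression by background, of expression level, of opposite signs of the sex-limited lists and of the splits for genes were fixed before.

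A difference between the array series was found for the Df(3L)ED4475 genes, whose log2 ratio was 0.11 higher on arrays 1 to 5 than on arrays 6 to 12 (exact permutation p = 0.0404), and white, whose difference was -1.32 (exact permutation p = 0.0215). The size for white depends on the offset, since its signal was below the blank limit in some channel on 4 of arrays 1 to 5, and with plain subtraction it was -3.94 (exact permutation p = 0.00379).

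On arrays 1 to 5 the Df(3L)ED4475 genes as a set showed no drop. With plain subtraction 14 of the 33 were lower in the samples labelled Df(3L)ED4475. Single genes went both ways, such as Lsp2 with a drop of 0.83 ± 0.22 (SE) and Miox with -0.73 ± 0.21, and 0 passed over the list alone. An exchange of the labels would place the set well above 0, but the upper 95% limit of its mean with plain subtraction was 0.08. Pulling of dim ratios to 0 would spare bright spots, but the brightest 11 genes had a median drop of -0.15, with an upper 95% limit of 0.13. That limit comes from resampling these genes, which are not independent, and leaves out the spread between arrays. By itself it does not exclude such pulling. Flies without the deletion in the samples labelled Df(3L)ED4475 there stay open and undecided, as does compensation of single copies: white, which marks both deletions, had a mean of -0.41 on arrays 1 to 5 with an upper 95% limit of 0.08, and its signal in these samples was below the blank limit on 4 of 5. This test replaced that of white between the series (exact permutation p = 0.0215), which rests on arrays 6 to 12 as well. For the samples labelled Df(3L)ED4543 on arrays 6 to 12, where white had a mean of 0.91, such flies were not tested, but their deleted genes did show a drop there (0.12, plain subtraction 0.24, 95% interval 0.08 to 0.39, exact permutation p = 0.0312) and white was above the blank limit on arrays 8 to 12.

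Over all arrays the genes of both deletion sets fell short of a drop of 1. These sets leave out margin genes, which may or may not be deleted. With plain subtraction on arrays 6 to 12, the 16 tested margin genes of Df(3L)ED4475 had a median log2 ratio of -0.62, against -0.49 for the set. On arrays 1 to 5 these margin genes had -0.07. With the same subtraction, the 31 tested margin genes of Df(3L)ED4543 had 0.18 on arrays 1 to 5 and -0.07 on arrays 6 to 12. Compression by background would let the brightest 14 deleted genes approach 1, but with plain subtraction over all arrays their median drop was 0.21, with an upper 95% limit of 0.44. Within arrays 6 to 12 the intervals also lay below 1, at 0.33 (0.05 to 0.75) for the brightest 11 Df(3L)ED4475 genes and 0.29 (0.06 to 0.48) for the brightest 3 Df(3L)ED4543 genes. Only for these 3 genes on arrays 1 to 5 did the interval reach 1, at 0.88 (-0.06 to 1.32). All these limits come from resampling genes, which are not independent, and leave out the spread between arrays. With 2 or 3 genes they are the lowest and the highest gene. By themselves they do not exclude compression. Whether background shapes the relation to expression level cannot be told apart, because no relation was past the threshold to begin with (rho -0.04 over 19 genes with plain subtraction and the stricter filter, against 0.19 over 41). Partial transcriptional compensation, mixed samples and cross-hybridisation are all open.

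Accessory gland and testis lists had medians above 0 and egg shell (-0.24) and ovary lists below 0. These opposite signs met the rule fixed before for different shares of the sexes. Over arrays, no difference from 0 was detected for the female lists (permutation p = 0.279 and 0.246), and on arrays 1 to 5 their medians were near 0. Under the condition added after the results were seen, that these lists also differ from 0, the signs do not decide. Different shares of males and females among the 25 flies of a sample may contribute, and the sexes are not given, but the arrays leave this open. Across the 12 arrays testis and egg shell medians had a Spearman's rho of -0.52 (permutation p = 0.0868), and accessory gland and egg shell -0.08 (p = 0.816; 95% interval -0.68 to 0.49), too wide to decide, while testis with ovary (-0.74, p = 0.00797, adjusted 0.0478) and with roX1 (0.63, p = 0.0306, adjusted 0.0612) go with such shares. Against this, Pearson's r for testis and ovary was -0.45 (p = 0.145), and within arrays 6 to 12 rho was 0.09 for testis with roX1 and 0.11 with accessory gland, where within arrays 1 to 5 it was 0.97 and 0.87. For testis with ovary r was -0.84 without the 2 arrays farthest from the median, and rho was -0.87 on arrays 1 to 5 and -0.81 on arrays 6 to 12. All these relations use offset medians, which shrink the arrays unevenly. Testis on array 1 had 0.10, against 0.76 with plain subtraction, and on array 4 it had 0.02 in both. How the relations depend on that setting was not tested. Chance over arrays is argued against for the testis list alone, by its adjusted sign-flip p of 0.0107. A difference between the lines in male gene expression itself stays open as well.

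Other splits of the arrays were made by exchanging the lines on some arrays with the dyes kept balanced. Of 100 splits, 26 called at least the 9 gene lists of the real one, and the highest other called 15, so chance is not excluded for the number of lists. The real count of genes was 0, which every split reaches, so the splits say nothing about chance for all genes or for genes outside the deletions (100 of 100 each, highest other 0) or within arrays 6 to 12 (35 of 35, highest other 0). Within arrays 1 to 5 the 10 splits are too few for a share under 0.05, with 0 genes in the real split and 0 as the highest other.

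On array 4 the odorant binding and pheromone list, at -0.27, lay far from arrays 1, 2, 3 and 5, the only such case in 50 sets examined, where chance gives about 1 in 20.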

How the results depend on the processing

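Alternatives with normexp without offset, with plain subtraction joined to the stricter filter, and with plain subtraction within a series were chosen after the data were seen. Of 674 comparisons with an alternative, 573 were labelled the same. For tests this meant the same direction and side of the threshold. For counts it meant an equal count or a count within a set factor of the main one, so counts of 0 that stayed 0 are included. Some comparisons could not change, since the deletion medians use neither the dye term nor the series term. The total is thus not a measure of robustness. The cause of the changes below was not tested, except where fewer arrays or genes were used. The count of genes, 0, became 1 with print-tip loess (LManV, which lies outside the deletions, where the count was also 1) and 0 to 2 on leaving out 1 array, the 2 being LManV and CG6277 without array 12. The Df(3L)ED4475 genes, at -0.06, passed the threshold with plain subtraction (-0.23), median centring (-0.06), no filter (-0.01), the mean in place of the median (-0.10), without the outermost 2 genes at each end (-0.07), and on arrays 6 to 12 (-0.10, plain -0.40), and turned sign on arrays 1 to 5 (0.01, plain 0.02). Leaving out 1 array gave -0.07 to -0.04, past the threshold without array 2 or array 8 (both -0.07). The Df(3L)ED4543 genes, at 0.20, lost the threshold on arrays 1 to 5 (0.32, plain 0.55) and 6 to 12 (0.12), and without the replicate block, that is without the pairing by shared array (0.20, permutation p = 0.196), and ranged from 0.14 to 0.22 on leaving out 1 array. Without the pairing the proteasome list (-0.05) also lost its call, and no other call on genes, deletions or the 9 called lists changed. The difference between the deletions ranged from -0.17 to -0.08 and turned to 0.17 with plain subtraction on arrays 6 to 12.

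The relation to expression level for Df(3L)ED4475, 0.09, was -0.15 without background correction and with plain subtraction, -0.23 on arrays 1 to 5, -0.17 in the deposited value table, -0.08 with plain subtraction and the stricter filter and -0.09 with plain subtraction on arrays 6 to 12, while it passed the threshold without a filter (0.39) and on arrays 6 to 12 (0.37); leaving out 1 array gave -0.02 (array 10) to 0.24. For Df(3L)ED4543, 0.62 became -0.14 with plain subtraction, -0.69 with it on arrays 1 to 5, -0.48 in the deposited table and 0.55 without a filter, and 0.29 to 0.81 on leaving out 1 array, past the threshold without array 5 (0.81). The stricter filter left 3 of its genes, too few for a value. Of 22 gene lists, 9 passed, against 16 on arrays 6 to 12, 5 with plain subtraction and the stricter filter, 5 with plain subtraction on arrays 1 to 5, and 5 (without array 12) to 12 on leaving out 1 array. On arrays 1 to 5 the egg shell list had 0.00 and the P450 list -0.04 (plain -0.09), and with plain subtraction the proteasome list 0.00. Accessory gland and testis kept their calls under all 30 alternatives, but these are calls with the preset correlation, and with an estimated correlation neither passed (adjusted p = 0.422 and 0.214), nor did accessory gland by sign-flip permutation over arrays (adjusted 0.308). Of the same 30, the call was lost with its direction kept in 3 for egg shell, 8 for ovary, 8 for heat shock, 6 for proteasome, 5 for transferases, 6 for digestive and 10 for P450. Leaving out 1 array gave -0.28 to -0.12 for egg shell (call lost without array 12, -0.13), -0.09 to -0.03 for ovary (lost without array 7, 8, 9 or 12), 0.02 to 0.09 for P450 (lost without array 7, 8, 9, 11 or 12) and 0.02 to 0.07 for digestive hydrolases (lost without array 11 or 12).

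Within arrays 1 to 5, the Df(3L)ED4475 genes had 0.00 without a filter and 0.00 to 0.01 on leaving out 1 array, and the Df(3L)ED4543 genes 0.19 to 0.40. Within arrays 6 to 12 the Df(3L)ED4475 genes had -0.13 to -0.07, the threshold being lost without array 6, 7, 9, 10, 11 or 12 (6 arrays cannot go below 0.0312). The Df(3L)ED4543 genes there passed it without background correction (0.26), with plain subtraction (0.24), print-tip loess (0.14), no filter (0.02) and the deposited values (0.27), and had 0.08 to 0.15 on leaving out 1 array, past it without array 6 (0.15). Signal over background limits all ratios on arrays 1 to 3, 6 and 7, where few probes lay above the blanks.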

Other observations

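The scan along the arms and both tests on it were chosen after the results were seen. In plain-subtracted ratios, runs of neighbouring genes with a running median (15 genes) beyond 0.5 were located on the arrays with 1 dye orientation and measured on the arrays with the other, within each series. On arrays 1 to 5 a run on 3L from CtsK1 to CG13476 (16 genes around the Df(3L)ED4543 set) was found by the scan with Df(3L)ED4475 in Cy5. It had 0.55 on the 3 held-out arrays (0.05 to 1.09), a value reached by 3 of 5657 runs of that length, itself included. On arrays 6 to 12 it had 0.17. The scan of these 5 arrays also located runs on 2R outside the deletions, Lcp2 to Mal-A4 and CG4363 to CG9304, which had 0.14 and 0.27 on the held-out arrays, reached by 1080 of 5702 and 763 of 5722 runs. On arrays 6 to 12 a run of 15 genes from CG6083 to CG10907, most of them margin genes, reached into the left end of the Df(3L)ED4475 set. It had -0.80 on the 3 held-out arrays (-1.35 to -0.06), reached by 1 of 5682 runs, and -0.10 on arrays 1 to 5. Located on the other orientation, a run of 5 margin genes from RIOK1 to Pldn had -1.02 on 4 held-out arrays (-1.57 to -0.58), reached by 4 of 5730 runs. Runs inside the set were less unusual: RhoGAP68F to Miox had -0.28 on held-out arrays (214 of 5732) and RhoGAP68F to thoc6 -0.34 (116 of 5720).

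A further run on arrays 6 to 12 lay outside both deletions, beyond the right limit of Df(3L)ED4543, from CG13465 to Pex3 (11 genes), and was lower in the samples labelled Df(3L)ED4475. Located with Df(3L)ED4475 in Cy5, it had -0.50 on the 3 arrays with the dyes exchanged (-0.75 to -0.19), reached by 20 of 5702 runs, which argues against dye bias. The run located on the other orientation, from CG12355 to CG12301, had -0.14 on its 4 held-out arrays (-0.37 to 0.20), reached by 794 of 5710 runs, so it was not unusual there. Joined over both orientations, each array measured on the run found without it, the value was -0.29 ± 0.31 (SD, n = 7; exact permutation p = 0.0625), below 0 on 6 of 7 arrays, and so not past the threshold. Fewer ovaries in these samples may also lower such genes: the run minus the ovary list was -0.12 ± 0.51 (n = 7, exact permutation p = 0.547), with a 95% interval from -0.59 to 0.35 too wide to decide. A second lesion or a strain difference in one line is a hypothesis that these arrays leave open.

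Some genes outside the deletions were lower in the samples labelled Df(3L)ED4475 on every one of arrays 1 to 5 with plain subtraction. Drsl6, an antifungal peptide family gene, had a mean of -3.96 there and 0.49 on arrays 6 to 12, and the P450 genes Cyp6a8 and Cyp6w1 had -1.35 and -1.09 against 0.68 and 0.70. Their interaction with the series did not pass limma's test (adjusted p = 0.136, 0.0533 and 0.244). These genes were named after their values were seen.

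Relations between the medians of sex-limited lists over the 12 arrays, 6 in all, were computed after the lists were seen, from offset ratios only. Testis and egg shell had a Spearman's rho of -0.52 (permutation p = 0.0868, adjusted 0.104), a Pearson's r of -0.43 (p = 0.166) and an r of -0.62 without the 2 arrays farthest from the median. Testis and ovary had -0.74 (p = 0.00797, adjusted 0.0478), -0.45 (p = 0.145) and -0.84. Testis and accessory gland had 0.65 (p = 0.0254, adjusted 0.0612), 0.80 (p = 0.00259) and 0.62. Accessory gland and egg shell had -0.08 (p = 0.816, adjusted 0.816), -0.14 (p = 0.653) and -0.11. Egg shell and ovary had 0.58 (p = 0.0517, adjusted 0.0776), 0.69 (p = 0.013) and 0.33. Testis and roX1 had 0.63 (p = 0.0306, adjusted 0.0612), 0.60 (p = 0.039) and 0.38. Within arrays 6 to 12 rho was -0.74, -0.81, 0.11, 0, 0.68 and 0.09 in that order, with testis and ovary alone under 0.05 (n = 7, exact permutation p = 0.0349). Within arrays 1 to 5 it was -0.67, -0.87, 0.87, -0.40, 0.40 and 0.97, with testis and roX1 alone under 0.05 (n = 5, exact permutation p = 0.0333). The relations of testis with accessory gland and with roX1 were thus not detected within arrays 6 to 12.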
